A study of Bos taurus with 45 samples.

How the data were processed

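Total RNA of single bovine demi-blastocysts was extracted with a column kit for small samples and made into libraries with the NuGEN Ovation SoLo system with bovine transcript depletion, per the labels' protocols. The authors deposited 1 table of whole-number read counts per gene, with 24616 Ensembl bovine genes and 45 libraries, and the deposited counts are not normalized. The submitters' processing notes name the builds UMD3.1 and bosTau8 and the package edgeR, without a version or role. The aligner, the counting program, and whether duplicate reads were removed are not given in the sources used here. Each column was matched to its sample by title, and each sample's group was taken from its pregnancy status label and its treatment from its culture label. The labels name each sample as a demi-blastocyst, so a replicate is an embryo.

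The gene identifiers were looked up in the supplied table of bovine gene symbols, and 0 of 24616 matched, so no gene name is given. The 30 gene lists, the lineage scores and the composition covariate fixed before the data were examined, and the rule for named genes, which chose genes with a symbol by p within each direction, need symbols and were not run. In their place at most 2 identifiers called higher and 2 called lower in each comparison are given, those with the smallest p, chosen after their values were seen. Copies and overlapping genes that share reads could not be marked without names, and strand use in counting is not given in the sources used here.

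Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the outcome group, libraries were scaled by TMM, dispersions were estimated with the default settings, and the quasi-likelihood F test was run with robust estimation. All 45 libraries entered 1 fit with outcome and culture treatment as terms. Lost and maintained were joined for the comparison of any pregnancy, and the interaction was fitted on maintained and not established libraries because only 1 lost library had CSF2. Benjamini-Hochberg adjustment at 0.05 was used. Levels are given in CPM of the library total. TMM factors lay between 0.91 and 1.67 in the 40 libraries above 1000000 counts and between 0.0267 and 0.493 in the other 5.

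Totals, numbers of genes with 5 or more counts, and the share of counts in core genes were compared by two-sided permutation tests, exact where a group had under 10 libraries and with 100000 resamples otherwise. Shares of embryos were compared by Fisher's exact test, with exact (Clopper-Pearson) 95% intervals, which cover counting error only. These used Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3. The gene test was run on simulated counts with 200 changed genes and with none, and on 100 splits of the 45 libraries and 60 splits of the 40 deeper ones, each number including the real split.

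The alternatives planned before the data were examined were DESeq2 1.42.0 in place of edgeR, DESeq2's size factors, limma 3.58.1 voom with sample quality weights, no filter on low counts, an adjusted p of 0.10, 2 surrogate variables from sva 3.50.0, fewer covariates, only the compared groups in the fit, each treatment alone, a replicate block, and each library left out in turn. Alternatives added after seeing the data were leaving out the 5 libraries under 1000000 counts (alone, with voom and with DESeq2), library totals without TMM, robust dispersions, edgeR's bias-adjusted deviance, and Fisher's exact test per gene on the number of libraries with 5 or more counts. The core genes were also defined after seeing the data. Low counts limit the precision of each value: 5 libraries hold under 1000000 counts, and a gene seen in few libraries gives a mean that rests on those few.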

Results

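RNA was sequenced from 45 bovine demi-blastocysts, each of which was one part of a day 7 blastocyst whose other part was transferred to a recipient cow. The embryos were made in vitro with sperm sorted to give female embryos and received 10 ng/ml of CSF2 or vehicle in the culture medium between day 5 and day 7. CSF2 is colony stimulating factor 2, a cytokine that the labels describe as able to raise the competence of blastocysts to survive after transfer. Recipients were examined at day 30 and day 60 of gestation. In 29 cases no pregnancy was found at day 30, a group called not established here, with 14 CSF2 and 15 vehicle embryos. In 6 cases a pregnancy seen at day 30 was gone by day 60, a group called lost, with 1 CSF2 and 5 vehicle embryos. In 10 cases the pregnancy was present at both examinations, a group called maintained, with 5 CSF2 and 5 vehicle embryos. The part that was sequenced is thus the sister of the part whose fate defines the group, and per the labels an uneven bisection sent the smaller or more damaged part to sequencing.

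The total count per library had a median of 5579779. In 40 libraries the total lay between 3906252 and 10326829 counts. The other 5 libraries lay below 1000000, with 853817 counts in not established replicate 8, 264574 in not established replicate 27, 475278 in not established replicate 29, 687331 in lost replicate 5 and 137808 in maintained replicate 8. Of the 24616 genes in the table, 11622 had no count in any library. The 40 deeper libraries had between 1095 and 6137 genes with 5 or more counts, and the 5 shallow libraries had between 50 and 502. A median of 83.7% of the genes stood at 0 in a library. The genes are named in the table by Ensembl identifiers only, which the files do not pair with gene names, so genes are given by identifier and no gene list or lineage marker is reported.

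**Figure D1:**
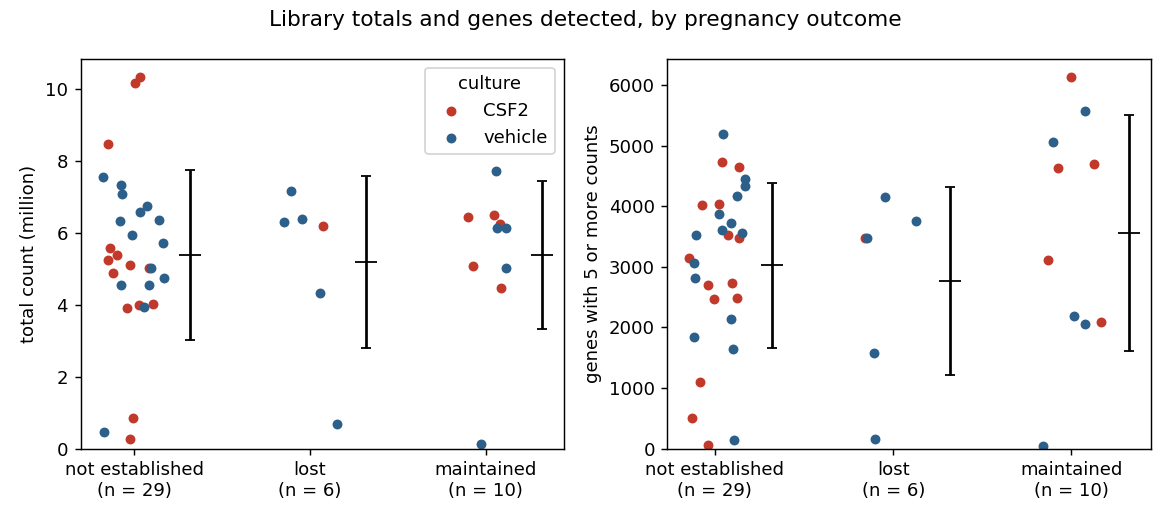
Total count (left) and number of genes with 5 or more counts (right) of each of the 45 libraries by pregnancy outcome, coloured by culture treatment, with the mean and SD of each group in black. The 3 outcome groups overlap in both measures, and 5 libraries lie below 1000000 counts.

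A set of 120 genes had 5 or more counts in each of the 40 deeper libraries, and these core genes held between 31.8% and 51.5% of a deeper library's counts. At the other end, 4479 genes reached 5 counts in only 1 to 4 of the 40 libraries. Genes read in a single library had a mean count of 434.8 in that library and a median of 137.5. Genes read in 17 to 24 libraries had a mean of 824 counts in the libraries that read them, and the core genes a mean of 19293 counts. A gene was therefore in a given library mostly either at 0 or well above the minimum of 5 counts, and the spread between embryos of one group was large for all genes named below.

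**Figure D2:**
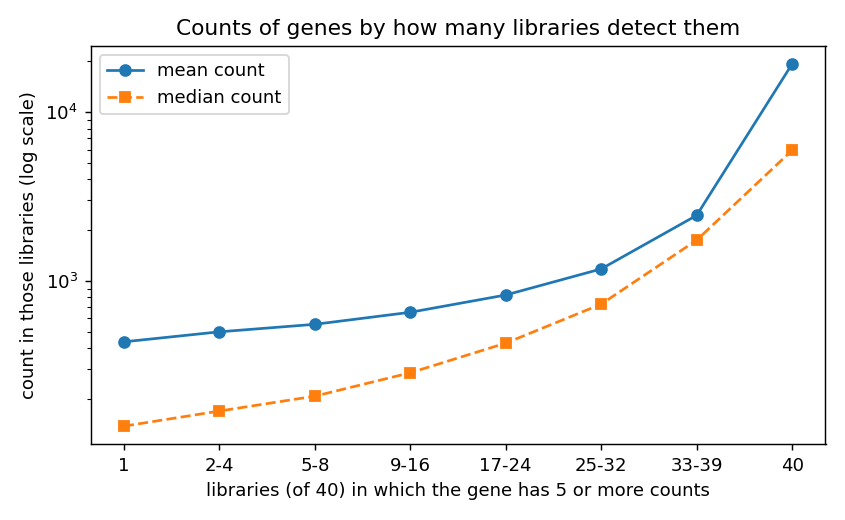
Mean (circles) and median (squares) count, on a log axis, of genes grouped by the number of the 40 deeper libraries in which they had 5 or more counts. The mean rises from 434.8 counts for genes read in 1 library to 19293 for those read in all 40.

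The outcome groups were first compared in the overall makeup of the libraries. The number of genes with 5 or more counts averaged 3560 ± 1948 (SD, n = 10) in maintained, 2769 ± 1555 (SD, n = 6) in lost and 3025 ± 1362 (SD, n = 29) in not established embryos. The difference in means between maintained and not established embryos was no larger than shuffled group labels often gave (two-sided permutation test, p = 0.345). The same held for maintained and lost embryos (exact permutation test, two-sided, p = 0.41) and for lost and not established embryos (exact permutation test, two-sided, p = 0.689). The core genes held 42.3% ± 11.7 (SD, n = 10) of the counts in maintained, 38.8% ± 5.66 (SD, n = 6) in lost and 40.1% ± 10.5 (SD, n = 29) in not established embryos. Shuffled labels often gave a difference as large as that between maintained and not established embryos (two-sided permutation test, p = 0.59). Among the 5 shallow libraries, maintained replicate 8 had a core share of 73.24%. Not established replicate 8 had 7.43%, below every deeper library, while not established replicates 27 and 29 had 70.48% and 65.12%. The direction turned without the 5 shallow libraries, with 38.9% ± 4.45 (SD, n = 9) in maintained and 39.2% ± 4.37 (SD, n = 26) in not established embryos (exact permutation test, two-sided, p = 0.838). Between the treatments, the core genes held 37.8% ± 10.6 (SD, n = 20) of the counts with CSF2 and 42.5% ± 9.49 (SD, n = 25) with vehicle (two-sided permutation test, p = 0.122). The shares without the 5 shallow libraries were 37.6% ± 2.94 (SD, n = 18) and 40.2% ± 5.27 (SD, n = 22; two-sided permutation test, p = 0.071). Over the 20 such tests of totals, genes detected and core genes on the 45 libraries, the smallest Benjamini-Hochberg adjusted p was 0.931.

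The main comparison set embryos whose sister part gave a maintained pregnancy against those whose sister part gave none. Among 6909 genes tested, 4 were called at an adjusted p below 0.05, all higher in maintained embryos (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). ENSBTAG00000047330 reached 5 counts in 5 of 10 maintained embryos and in 0 of 29 not established embryos. Its level was 29.6 ± 51.6 CPM (counts scaled to a library total of 1000000; SD, n = 10) in maintained embryos, and the 29 not established libraries held 3 counts of it in all (adjusted p = 0.0023, edgeR). Maintained replicate 4 held 55.1% of the summed CPM of this gene in the maintained group. ENSBTAG00000020233 had 2183 ± 5734 CPM (SD, n = 10) in maintained and 429 ± 396 CPM (SD, n = 29) in not established embryos (adjusted p = 0.0048, edgeR). Maintained replicate 8, which had 137808 counts, held 84.6% of the maintained group's sum. Without the 5 shallow libraries, the same gene had 373 ± 357 CPM (SD, n = 9) against 479 ± 389 CPM (SD, n = 26), so the direction turned. ENSBTAG00000047330 stayed called there (adjusted p = 0.00458, edgeR), whereas the fitted log2 change of ENSBTAG00000020233 went from 5.42 to -0.37. Without not established replicate 8 alone, the latter gene lost its call (adjusted p = 0.0844, edgeR) with a log2 change of 5.41, as large as before. These identifiers, and all those below, have the smallest p in their comparison and direction and were chosen after their values were seen.

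The number called in this comparison was 10 without the 5 shallow libraries, 0 with limma voom and 73 with DESeq2, of which 47 were higher and 26 lower. In edgeR, 40 were called higher and 52 lower at an adjusted p of 0.10, 18 higher and 20 lower with 2 surrogate variables, 3 higher and 1 lower with library totals, 42 higher and 4 lower with bias-adjusted deviance, and 1091 higher and 558 lower with no filter. CSF2 libraries alone gave 871 higher and 42 lower, vehicle libraries alone 9 higher and 0 lower, and DESeq2 without the 5 shallow libraries 78 higher and 35 lower. With DESeq2's size factors 7 were called, all higher, and ENSBTAG00000020233 lost its call there (log2 change 4.11, adjusted p = 0.0875) and with library totals (1.98, adjusted p = 0.39). That gene also lost its call with 2 surrogate variables (log2 change 3.34, adjusted p = 0.108, edgeR). Fisher's exact test of the number of embryos in which each gene reached 5 counts called 0 of 8102 genes, and 230 of them (2.8%) had an unadjusted p below 0.05.

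**Figure D3:**
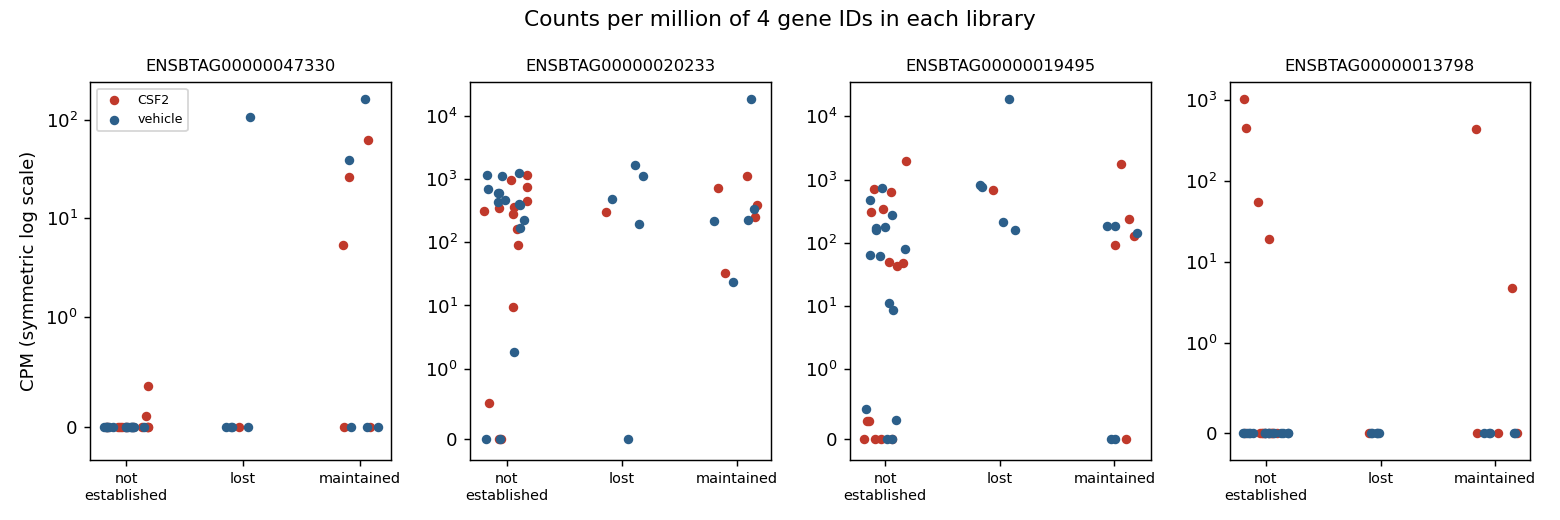
CPM, on a symmetric log axis, of 4 gene identifiers in each of the 45 libraries by pregnancy outcome, coloured by culture treatment. Points at 0 are libraries with no count. ENSBTAG00000047330 and ENSBTAG00000013798 are at 0 in most libraries, and ENSBTAG00000020233 and ENSBTAG00000019495 are above 0 in most.

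Maintained and lost pregnancies were compared to ask whether embryos of pregnancies that ended between the examinations differed from the rest. All 32 genes that edgeR called of 6909 were lower in maintained embryos. DESeq2 gave the opposite balance, with 441 genes higher and 23 lower, and 499 higher and 29 lower without the 5 shallow libraries. These were mostly other genes, since with all libraries 3 of its calls were among edgeR's 32. With all libraries DESeq2 gave no adjusted p for the identifiers named next, so it could not call them. The small overlap is thus partly built in, and why these values are missing was not examined. ENSBTAG00000019495 had 270 ± 523 CPM (SD, n = 10) in maintained and 3554 ± 7423 CPM (SD, n = 6) in lost embryos (adjusted p = 1.2e-06, edgeR), with 5 or more counts in 7 of 10 and 6 of 6. ENSBTAG00000013858 had 127 ± 227 CPM (SD, n = 10) in maintained and 1034 ± 1901 CPM (SD, n = 6) in lost embryos (adjusted p = 0.00026, edgeR). Lost replicate 5, a library of 687331 counts, held 87.7% of the lost group's sum of the first gene and 78.9% of that of the second. Without the 5 shallow libraries the lost embryos had 526 ± 316 CPM (SD, n = 5) of the first gene against 300 ± 545 CPM (SD, n = 9) in maintained embryos, and 0 genes were called by edgeR. Without lost replicate 5 alone, 1 gene was called in all, and the log2 change went from -10.16 to -1.63 for ENSBTAG00000019495 (adjusted p = 0.765, edgeR) and from -9.07 to -1.69 for ENSBTAG00000013858 (adjusted p = 0.768, edgeR). Without not established replicate 8 both calls also ended (adjusted p = 0.0529 and 0.063), but the log2 changes stayed at -10.19 and -9.12. With all libraries kept, another scaling ended both calls with smaller log2 changes, which were -5.58 (adjusted p = 0.125) and -4.38 (adjusted p = 0.125) with DESeq2's size factors in edgeR, and -4.57 (adjusted p = 0.138) and -3.54 (adjusted p = 0.216) with library totals. Without not established replicate 27 the second call ended (adjusted p = 0.0548) at a log2 change of -9.13. Both calls ended with 2 surrogate variables in edgeR, at log2 changes of -7.41 (adjusted p = 0.204) and -7.62 (adjusted p = 0.18).

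Lost pregnancies were also compared with those not established, and edgeR called 60 genes, 59 higher and 1 lower in lost embryos. DESeq2 gave the opposite balance, with 19 genes higher and 464 lower, and 29 higher and 537 lower without the 5 shallow libraries. With all libraries 6 of its calls were among edgeR's 60. It gave no adjusted p for ENSBTAG00000019495 or ENSBTAG00000002755 and so could not call them, which lowers the overlap by construction. ENSBTAG00000019495 was again the gene with the smallest p among those higher, with 218 ± 406 CPM (SD, n = 29) in not established embryos (adjusted p = 3.8e-12, edgeR). ENSBTAG00000002755 had 3579 ± 8414 CPM (SD, n = 6) in lost and 169 ± 213 CPM (SD, n = 29) in not established embryos (adjusted p = 7.3e-10, edgeR). With DESeq2's size factors in edgeR both stayed called with smaller log2 changes, of 5.82 against 10.12 for ENSBTAG00000019495 and 5.42 against 9.77 for ENSBTAG00000002755, and with library totals these were 4.67 and 4.22. With 2 surrogate variables both calls ended (adjusted p = 0.121 for each, edgeR), at log2 changes of 7.7 and 11.62. Lost replicate 5 held 96.6% of the lost group's sum of ENSBTAG00000002755, and without the 5 shallow libraries its level was 144 ± 136 CPM (SD, n = 5) in lost and 188 ± 217 CPM (SD, n = 26) in not established embryos, which turns the direction. ENSBTAG00000013981, the 1 gene called lower, had no count in 6 lost embryos and reached 5 counts in 18 of 29 not established embryos, with 137 ± 366 CPM (SD, n = 29; adjusted p = 0.035, edgeR). Its call ended without any one of the 6 lost embryos or not established replicate 25, with adjusted p from 0.0625 to 0.126, although the remaining lost embryos still had no count, and it ended with DESeq2's size factors (adjusted p = 0.0787) and library totals (adjusted p = 0.103). Without the 5 shallow libraries its adjusted p was 0.153 with edgeR, 0.014 with limma voom and 6.1e-08 with DESeq2. Without lost replicate 5, ENSBTAG00000019495 was no longer called (adjusted p = 0.646), and 20 genes were called in this comparison, and 5 of them were among the 60.

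All 16 pregnancies seen at day 30, lost and maintained together, were set against the 29 not established, which asks about the establishment of pregnancy whatever followed. Of 6909 genes, 35 were called higher and 16 lower in embryos that gave a pregnancy. ENSBTAG00000005869 had 978 ± 2630 CPM (SD, n = 16) with pregnancy and 156 ± 178 CPM (SD, n = 29) without (adjusted p = 0.00099, edgeR). ENSBTAG00000006982 had 500 ± 1404 CPM (SD, n = 16) with pregnancy and 96.4 ± 146 CPM (SD, n = 29) without (adjusted p = 0.00099, edgeR). With DESeq2's size factors in edgeR both calls ended, with log2 changes of 3.31 against 7.05 (adjusted p = 0.089) and 2.87 against 6.55 (adjusted p = 0.151), and with library totals these were 2.53 (adjusted p = 0.217) and 2.04 (adjusted p = 0.595). Lost replicate 5 held 68.8% and 71.8% of the pregnancy group's sum of these genes, and without it their log2 changes went from 7.05 to 1.01 (adjusted p = 0.977, edgeR) and from 6.55 to 0.66 (adjusted p = 1, edgeR). Both also lost their calls without not established replicate 8 or 27 (adjusted p from 0.078 to 0.0864), where the log2 changes did not shrink, at 7.27 for the first and 6.54 to 6.55 for the second. ENSBTAG00000026882 had no count in 16 embryos with pregnancy and reached 5 counts in 6 of 29 without (adjusted p = 0.0073, edgeR). Not established replicate 6 held 48.6% of the sum of this gene in the second group. Over the alternative settings other than leaving out single libraries, its call was kept in 9 and not kept in 5. ENSBTAG00000004368 had 0.913 ± 2.14 CPM (SD, n = 16) with pregnancy and 109 ± 290 CPM (SD, n = 29) without (adjusted p = 0.0017, edgeR), and not established replicate 8 held 47.3% of the sum in the second group and ended the call when left out (adjusted p = 0.196, edgeR), where the log2 change went from -8.61 to -6.47. Its call also ended with DESeq2's size factors in edgeR, at a log2 change of -9.9 (adjusted p = 0.0568). Without the 5 shallow libraries its level was 1.04 ± 2.27 CPM (SD, n = 14) with pregnancy and 64.2 ± 117 CPM (SD, n = 26) without, with an adjusted p of 0.275 in edgeR and 0.0161 in DESeq2. With DESeq2's size factors in place of TMM, 7 genes were called higher and 10 lower, and with library totals alone 9 higher and 15 lower. Without the 5 shallow libraries 23 were called higher and 23 lower. The excess of higher calls held with DESeq2's own test (34 higher and 10 lower), which gave 69 and 13 without the 5 shallow libraries, and in edgeR without the treatment term (61 and 21), with bias-adjusted deviance (110 and 72) and at an adjusted p of 0.10 (54 and 25). It did not hold with 2 surrogate variables (47 and 70) or with no filter on low counts (1399 and 1620).

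CSF2 and vehicle were compared with the outcome group in the model. Outcome was seen only after the day 7 harvest and may itself depend on CSF2. The comparison is thus between embryos of like outcome, and need not equal the whole effect of the cytokine on the day 7 embryo. Of 6909 genes, 38 were called higher and 15 lower with CSF2. ENSBTAG00000001741 reached 5 counts in 6 of 20 CSF2 and 1 of 25 vehicle embryos, with 164 ± 482 CPM (SD, n = 20) and 1.55 ± 7.71 CPM (SD, n = 25), respectively (adjusted p = 2e-05, edgeR). Not established replicate 25, which had the fewest genes detected of the 40 deeper libraries (1095), held 62.3% of the CSF2 sum. Leaving out each library in turn gave log2 changes between 8.19 and 12.94, against 12.56 with all libraries. ENSBTAG00000013798 reached 5 counts in 6 of 20 CSF2 embryos, with 100.2 ± 258 CPM (SD, n = 20), and had no count in 25 vehicle embryos (adjusted p = 2.9e-05, edgeR). Not established replicate 25 held 51.4% of the CSF2 sum of this gene as well. Its log2 change lay between 12.15 and 12.38 with each library left out in turn. With no count in the vehicle group, the size of this change depends on the small count added in the fit. The narrow range is therefore no sign of a stable result. Over the alternative settings other than leaving out single libraries, its call was kept in 9 and not kept in 5. ENSBTAG00000018321 had no count in 20 CSF2 embryos and reached 5 counts in 7 of 25 vehicle embryos (adjusted p = 0.0021, edgeR). ENSBTAG00000003608 had 2 counts in all over the CSF2 embryos and reached 5 counts in 7 of 25 vehicle embryos, with 77.3 ± 226 CPM (SD, n = 25; adjusted p = 0.0021, edgeR). Not established replicate 16 held 54.3% of the vehicle sum of ENSBTAG00000018321, and not established replicate 19 held 54.3% of that of ENSBTAG00000003608. With each library left out in turn, their log2 changes lay between -8.99 and -7.4 and between -11.19 and -10.43. These ranges likewise rest on a group with almost no counts. Over the alternative settings other than leaving out single libraries, each call was kept in 11 and not kept in 3. In the median gene called higher, 6 CSF2 and 2 vehicle embryos reached 5 counts, and a single CSF2 library held 60.5% of the group's summed CPM. The balance of higher and lower calls differed between settings. DESeq2 called 41 genes higher and 70 lower, and without the 5 shallow libraries edgeR called 26 higher and 24 lower and DESeq2 50 higher and 98 lower. The excess of higher calls held in edgeR with DESeq2's size factors (70 higher and 17 lower), with library totals (29 and 14), with bias-adjusted deviance (135 and 68), without the outcome term (97 and 62), with 2 surrogate variables (61 and 49) and at an adjusted p of 0.10 (87 and 49), and not with no filter on low counts (1525 and 1687). Of the 50 genes edgeR called without the 5 shallow libraries, 22 were among the 53, the 4 identifiers named here included, while limma voom called 0 with all libraries. Not established replicate 25 is not among those 5 libraries.

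Whether the difference between maintained and not established embryos depended on CSF2 was tested by an interaction term. Of 4603 genes, 3 were called, each with a lower value of the term (edgeR quasi-likelihood test, adjusted p below 0.05), and 0 were called without the 5 shallow libraries, where DESeq2 called 110 higher and 33 lower.

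**Figure D4:**
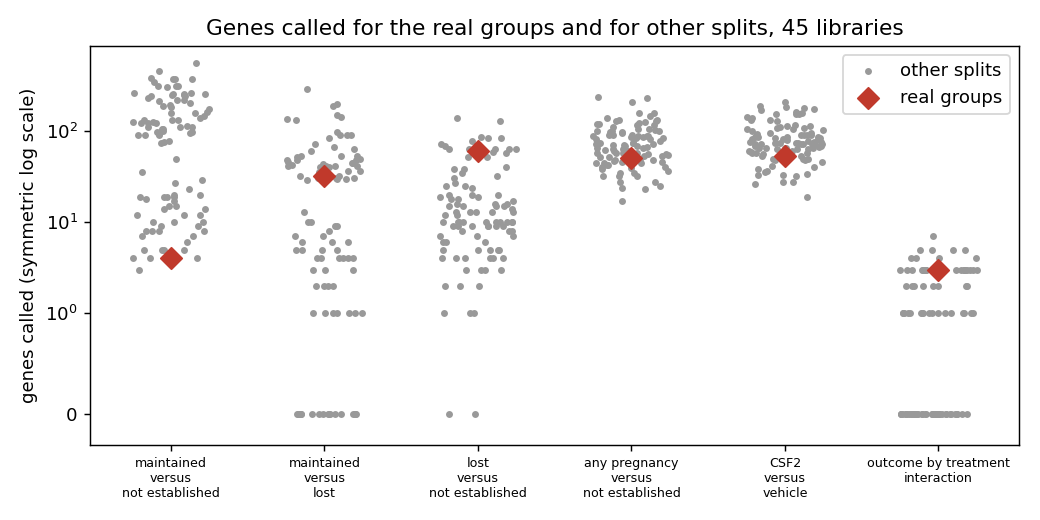
Number of genes called, on a symmetric log axis, in each of 6 comparisons for the real groups (diamonds) and for other random splits of the same 45 libraries into groups of the same sizes (grey points). The real numbers, from 3 to 60, lie within the range of the other splits in each comparison.

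The unadjusted p-values were below 0.05 for 8.1% of genes for maintained against not established, 16.7% for maintained against lost and 17.2% for lost against not established. On simulated counts with no changed gene, drawn for 45 libraries, the same test called 2 of 6427 genes for maintained against not established and 37 of 6409 for CSF2 against vehicle. With 200 genes changed 32-fold, it called 31% of them in the first and 39.5% in the second comparison, along with 107 and 77 unchanged genes. With 200 genes changed 4-fold, it called 5% and 2.5% of them, along with 63 and 42 unchanged genes. In these single simulations edgeR thus mostly missed differences of 4-fold in genes drawn at random. Genes with many counts were not examined apart, and the other comparisons were not simulated.

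The sequenced embryos were also counted by outcome and treatment. At day 30, 6 of 20 CSF2 embryos (30%, exact 95% interval 11.9% to 54.3%) and 10 of 25 vehicle embryos (40%, exact 95% interval 21.1% to 61.3%) had given a pregnancy (Fisher's exact test, two-sided, p = 0.544). At day 60 there were 5 of 20 and 5 of 25 (Fisher's exact test, two-sided, p = 0.731). Of the pregnancies seen at day 30, 1 of 6 with CSF2 and 5 of 10 with vehicle were lost (Fisher's exact test, two-sided, p = 0.307). None of these shares differed by more than sampling allows, and they describe the sequenced embryos, not all embryos transferred.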

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

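All predictions for the tests in this part were written after the results they bear on, or values close to them, had been seen, including those for the random splits, which had been planned.

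In groups of 6 or 10 libraries, 9 of 13 sets of values had a library far from the others. The not established group was not put to this rule, so not established replicate 8, with a core share of 7.43%, could not be flagged. The rule used flags about 1 in 20 sets of normally distributed values. Most of the sets are CPM values of single genes, which are skewed, so that rate need not hold for them. Maintained replicate 8 stood apart with a total of 137808 counts, a core gene share of 73.24% and 18470 CPM of ENSBTAG00000020233. Lost replicate 5 stood apart with 18700 CPM of ENSBTAG00000019495, 4900 CPM of ENSBTAG00000013858 and 20750 CPM of ENSBTAG00000002755. Among deeper libraries, maintained replicate 4 had 163.1 CPM of ENSBTAG00000047330, maintained replicate 10 had 1738 CPM of ENSBTAG00000019495 and maintained replicate 1 had 728.8 CPM of ENSBTAG00000013858. Most of these genes were picked for a small p, which favours genes with extreme libraries. The interaction of outcome and treatment, which tests whether the outcome difference differs between CSF2 and vehicle, called 3 genes.

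For none of the 6 comparisons could chance be excluded by other splits of the 45 libraries. For maintained against not established, 99 of 100 splits gave as many as the 4 genes called, with 555 the highest of the others. For maintained against lost, 41 gave as many as 32 (highest other 288), and for lost against not established 14 gave as many as 60 (highest other 139). For any pregnancy, 73 gave as many as 51 (highest other 237), for CSF2 81 gave as many as 53 (highest other 208), and for the interaction 31 gave as many as 3 (highest other 7). Some splits called several times the real number, which can come from a structure of the samples or from false calls of the test, and these were not told apart by a test. Counts were also simulated with no changed gene and no such structure. The test then called 37 genes for CSF2 with 45 libraries and 34 with the 40 deeper ones. For maintained against not established it called 2 and 11, where the other splits had medians of 97 and 5 and highest values of 555 and 520. Each is a single simulation, which is not of a kind with the highest of many splits. The simulated counts followed library totals alone, without the small TMM factors of the shallow libraries. False calls tied to those factors could thus not appear in them. With the 40 deeper libraries the highest other split fell from 288 to 11 genes for maintained against lost, from 139 to 24 for lost against not established and from 7 to 0 for the interaction. For maintained against not established the highest was 520, while the median of the other splits fell from 97 to 5. For any pregnancy and CSF2 the highest were 310 and 161, and the medians were 70 and 79 against 71 and 75 with all libraries.

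The genes called for lost against not established embryos may rest on 1 shallow library. Lost replicate 5 had a TMM factor of 0.0267, and without it 5 of the 60 genes remained called. With the 5 shallow libraries left out, 3 genes were called, and 45 of 60 splits gave as many, so an effect of pregnancy loss cannot be told apart from chance with 5 lost embryos left. The test was not simulated for this comparison, so how large an effect the 3 genes leave room for is not known.

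Of the genes in the table, 4479 were read in only 1 to 4 of the 40 deeper libraries, and a candidate explanation is that few molecules of each were captured and each was read many times. Genes read in a single library had a mean count of 434.8 there, far above the minimum of 5. That mean leaves out counts of 1 to 4, which shallow sequencing would also leave. The 26 deeper not established libraries averaged 3904 genes with 1 or more counts and 3347 with 5 or more. The mean alone therefore cannot tell the explanations apart. Too few reads per library remained open, with a Spearman correlation of 0.42 between total and genes detected over the 40 deeper libraries (Pearson 0.40, permutation p = 0.01 and 0.0069 for Spearman; Pearson 0.37 without the 2 farthest totals). The Spearman correlation was 0.58 within the 26 not established and -0.03 within the 9 maintained libraries. Expression that is truly on in some embryos and off in others was not tested, and stays open.

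For the genes called higher with CSF2, 1 library holding most of the reads may account for part of the size of the difference. In the median of the 38 genes, the top CSF2 library held 60.5% of the summed CPM, and it held over 50% in 26 of them. Among 1880 uncalled genes read in 5 to 7 CSF2 embryos the median was 49.1%, so a large share in 1 library was also common among uncalled genes. Whether CSF2 itself acted on these genes stays open, since chance could not be excluded by the splits.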

How the results depend on the processing

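Results without the 5 shallow libraries, with library totals, with robust dispersions, with bias-adjusted deviance and from detection were added after seeing the data. Numbers of genes called are given in the order maintained against not established (4), maintained against lost (32), lost against not established (60), any pregnancy (51), CSF2 (53) and interaction (3). DESeq2's Wald test called 73, 464, 483, 44, 111 and 101, and limma voom 0, 1, 4, 0, 0 and 0. With DESeq2's size factors edgeR called 7, 1, 18, 17, 87 and 0, and with library totals 4, 1, 13, 24, 43 and 0. With no filter it called 1649, 387, 540, 3019, 3212 and 406, over more genes tested. At an adjusted p of 0.10 it called 92, 75, 88, 79, 136 and 3, a wider threshold by construction. With 2 surrogate variables it called 38, 18, 29, 117, 110 and 0, and with bias-adjusted deviance 46, 95, 133, 182, 203 and 10. Without the 5 shallow libraries edgeR called 10, 0, 3, 46, 50 and 0, voom 0, 1, 11, 0, 0 and 0, and DESeq2 113, 528, 566, 82, 148 and 143. Detection tested by Fisher's exact test called 0 in the 5 comparisons it covers, with and without the shallow libraries. In maintained against lost the groups were too small for a gene to pass on its own, even with complete separation. The 0 there was thus close to fixed by group size. Robust dispersions gave the main numbers. Without the treatment term 5, 32, 82 and 82 genes were called in the 4 outcome comparisons, and CSF2 without the outcome term called 159. With only the 2 groups in the fit, 1, 1 and 40 were called. Maintained against not established called 9 in vehicle and 913 in CSF2 embryos alone, with 10365 genes tested in the latter. Except where construction is named, the cause was not tested.

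With the replicate block the numbers were 5, 5, 4, 0, 1 and 0. The numbers in the titles do not pair the embryos: 0 of 19 same-numbered pairs of deeper libraries had a correlation of deviations above 0.1 (mean 0.008), and 2 of 40 libraries correlated best with their own number in another group.

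Leaving out each library gave 3 to 26 genes for maintained against not established, 1 to 58 for maintained against lost, 20 to 93 for lost against not established, 34 to 124 for any pregnancy, 28 to 145 for CSF2 and 0 to 4 for the interaction. In the first 5 of these the highest number came without a lost library, where a smaller group size also lets more genes pass the filter by construction, and for the interaction, which holds no lost library, it came without not established replicate 5. The lowest came without lost replicate 5 for both comparisons of lost alone (1 and 20), and without not established replicate 8 for CSF2 (28). The interaction called 0 without maintained replicate 8 or 3.

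The direction of ENSBTAG00000020233 in maintained against not established reversed to a log2 change of -0.37 without the shallow libraries, -0.26 there with DESeq2 and -0.16 without maintained replicate 8, against up to 5.72 without any other library. That of ENSBTAG00000002755 in lost against not established reversed to -0.59, -0.75 with DESeq2, -0.44 without lost replicate 5 (up to 10.26 without another library) and -1.61 with the replicate block, and that of ENSBTAG00000004368 in any pregnancy to 0.72 with the block. The other named identifiers kept their direction. Differences in totals, genes detected, core share and pregnancy shares stayed short of the threshold throughout. The gene lists, lineage scores and composition covariate were not run, for lack of gene names. DESeq2 was not run on the other splits or on simulated counts, so its larger numbers have no such check.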

Other observations

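The similarity and detection tests in this part were chosen after seeing the data. Averaged over all pairs, embryos with the same outcome were not detectably more alike than embryos with different outcomes. Most pairs within an outcome joined not established embryos, so likeness among maintained or among lost embryos was hardly tested. Over 8456 genes in the 40 deeper libraries, the Spearman correlation between embryos, which is across genes, averaged 0.355 within an outcome group and 0.358 between groups (permutation of labels, one-sided, p = 0.64). By treatment the averages were 0.357 within and 0.356 between (p = 0.33). Single pairs lay between 0.25 and 0.47.

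ENSBTAG00000047330 was read in 6 of the 16 embryos that gave a pregnancy and in 0 of 29 that did not (Fisher's exact test on detection, unadjusted p = 0.000983, adjusted p = 1 over 8430 genes). In the 40 deeper libraries it was read in 6 of 14 and 0 of 26 embryos (Fisher's exact test, unadjusted p = 0.000782, adjusted p = 1). The difference fails the correction for the number of genes. Over the 45 libraries it shared the smallest unadjusted p by detection with 1 other gene, which had the same numbers. In the deeper libraries another gene had a smaller p (12 of 14 and 7 of 26 embryos, Fisher's exact test, unadjusted p = 0.000653, adjusted p = 1).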
